A study of Mus musculus with 7 samples.

How the data were processed

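RNA from sorted mouse cardiomyocytes was sequenced at postnatal day 6 (P6, 4 libraries) and postnatal day 30 (P30, 3 libraries). Per the labels, Rosa-Tom or Rosa-Cas9 mice received AAV9-cTNT-Cre on day 1, and cells were isolated by retrograde collagenase perfusion and fluorescence-activated sorting. RNA was taken from the sorted cells, 10 ng was copied with SMART-Seq v4 in 8 PCR cycles, 500 pg of cDNA went into Nextera XT libraries, and these were read on a NextSeq500. The labels differ on age: the treatment text gives collection at P14, while titles, ages and series design give P6 or P30, which were used here. The allele carried by each single mouse is not stated, and neither is whether libraries came from separate animals.

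The authors deposited a table of raw counts per gene, made with CASAVA 1.8, STAR 2.5.3a and featureCounts from Subread 1.5.2 on mm10, per the labels. The strand setting, the annotation and the treatment of multi-mapping or overlapping reads are not given in the sources used here, so counts of genes with pseudogenes (ribosomal proteins, Gapdh) and of genes that overlap others (Cpt1b with Chkb) are uncertain. The count columns carry the letters a to d and a to c, which the labels tie to no title number; the columns were grouped by the age in their names. A further table deposited by the authors holds, per the file headers, a DESeq2 comparison of the ages. Its baseMean is a signal that the authors averaged over libraries as size-factor-scaled counts. Its fold changes and their standard errors are on the log2 scale, per the file headers. The Wald statistic is a score deposited by the authors, and the p-value and adjusted p-value columns are theirs too. The labels list DESeq2 without a version. Computed again from the counts with median-of-ratios size factors, baseMean was the same within a relative tolerance of 1e-06 in 19954 of 19954 genes with a count, and the sign of the fold change was found to be P30 over P6.

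The count table had 23337 genes, of which 3383 had no count in any library. By symbol 20953 matched GENCODE mouse release 21 (GRCm38), and 22872 matched when older symbols were used; coordinates, transcript lengths and GC content came from that annotation. Mitochondrially encoded genes had no entry, so their share of counts was not analysed here. The number of genes with a count was 14476, 15108, 15692 and 14526 in P6a to P6d and 18223, 15720 and 16711 in P30a to P30c. Libraries were compared in pairs before they were averaged, and the lowest chi-square per gene within an age was 13.0, far above the value of 1 that sampling noise gives.

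Genes were tested with edgeR 4.0.16 in R 4.3.3: filterByExpr by age, TMM factors, and a quasi-likelihood fit of age with no covariate. P-values were adjusted by Benjamini-Hochberg over 12561 tested genes with a threshold of 0.05, and a second count asked for an absolute log2 fold change of at least 1. Log2 fold changes are P30 over P6 with their SE, CPM values use TMM-scaled library sizes, and group values are mean ± SD. With 4 and 3 libraries, p-values measure the spread between these libraries. Tests were tried on simulated data made from the fitted model, with 200 of 12561 genes set to change 2-fold or 4-fold. Over 5 simulations the procedure found 73.8% of genes set to change 2-fold and 95.6% of those set to change 4-fold, with 2.71% of calls false. Far more genes were called in the real comparison, where these shares may differ.

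A total of 32 gene lists, written from general knowledge of heart development before the values were seen, cover sarcomere, cell cycle, metabolic, electrical, growth, translation, regulator, stress and immune genes and markers of other cell types. Lists with at least 5 tested members (29) were tested by camera in limma 3.58.1 with a preset inter-gene correlation of 0.01, again with an estimated correlation, and by fry. Members were counted at the threshold over all genes and adjusted over the list alone. Shares within 16 pairs of paralogous genes and 11 measures of library composition were taken from raw counts in each library and tested by an exact permutation test over all 35 splits into 4 and 3, with adjustment over the pairs or measures.

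The genes named were set by a rule written before the values were seen. It takes the 10 largest rises and 10 largest falls among genes past the threshold with a mean CPM of at least 10 and no overlap between ages, leaving out predicted, Rik, mitochondrial, ribosomal RNA and pseudogene symbols. It adds, for each list, the 2 most counted members past the threshold in the prevailing direction, the 1 with the largest change at a mean CPM of at least 1, and the most counted member past it in the other direction. The genes of the pairs, Nppa, Nppb, Ryr2, Atp2a2, Igf2, H19, Mki67, Ppara, Ppargc1a, Esrra, Srf and the 5 most counted genes at each age complete it, for 138 genes. Other genes are said to be chosen after their values were seen. Some genes that the rule names entered every test and count and are not reported here.

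Alternatives planned before the values were seen were DESeq2 size factors, upper-quartile scaling and library totals in place of TMM; the DESeq2 1.42.0 Wald test, limma-voom and glmTreat in place of the quasi-likelihood test; no low-count filter, or a mean CPM of at least 10; leaving out the 10 most counted genes; thinning to the smallest library; leaving out each library; and other thresholds in the authors' deposited table. Removal of transcript length and GC trends, the use of P6a and P6b alone or P6c and P6d alone, subtraction of a background, a block by column letter and the exact test of list medians were added after seeing the data. Tables and plots were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.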

Results

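Gene expression was measured by RNA sequencing in cardiomyocytes purified from mouse hearts at postnatal day 6 (P6, 4 libraries) and postnatal day 30 (P30, 3 libraries). The pups carried a Rosa26 reporter or Cas9 allele and received, on day 1, an adeno-associated virus (AAV9) that expresses Cre recombinase from the cardiac troponin T promoter; labelled cells were collected by fluorescence-activated sorting after collagenase perfusion of the heart. Because the virus was given on day 1 at both ages, time since the virus rose with age, and the comparison cannot tell them apart. The deposited table gave whole read counts for 23337 genes. The libraries are named here by the letters of their columns, P6a to P6d and P30a to P30c. Total counts were 10594932, 27506075, 51427646 and 11515303 in P6a to P6d and 19368717, 16306173 and 15555469 in P30a to P30c. At these depths 3 counts corresponded to between 0.0583 CPM (counts scaled to library size) in P6c and 0.283 CPM in P6a. The labels do not say whether the libraries came from separate animals, so the p-values measure the spread between these libraries, which may be partly technical. No library duplicated another: the Spearman correlation over genes was 0.957 to 0.975 between libraries of the same age and 0.934 to 0.952 between ages.

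The comparison asked how the transcriptome of cardiomyocytes at P30 differed from that at P6. Between these ages transcripts of mitosis and of the slow skeletal troponin I gene fell, and transcripts rose for enzymes that break down ketone bodies and branched-chain amino acids, some calcium-handling genes and several sarcomere genes. Tnni1, the fetal troponin I, went from 2227 ± 90.1 CPM (SD, n = 4) to 1.22 ± 1.14 CPM (SD, n = 3), a log2 fold change of -10.89 ± 0.42 (SE). Hmmr, a mitotic spindle gene, fell from 42.7 ± 8.10 to 0.672 ± 0.405 CPM, and Igf2, a fetal growth factor, from 77.0 ± 10.4 to 5.23 ± 1.55 CPM. In the other direction, Oxct1, the rate-limiting enzyme of ketone body use, rose from 359 ± 25.9 to 1863 ± 199 CPM, and Ryr2, the calcium release channel of the sarcoplasmic reticulum, from 759 ± 46.3 to 1815 ± 234 CPM. The plot of CPM in each library shows these genes beside others named below.

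**Figure D1:**
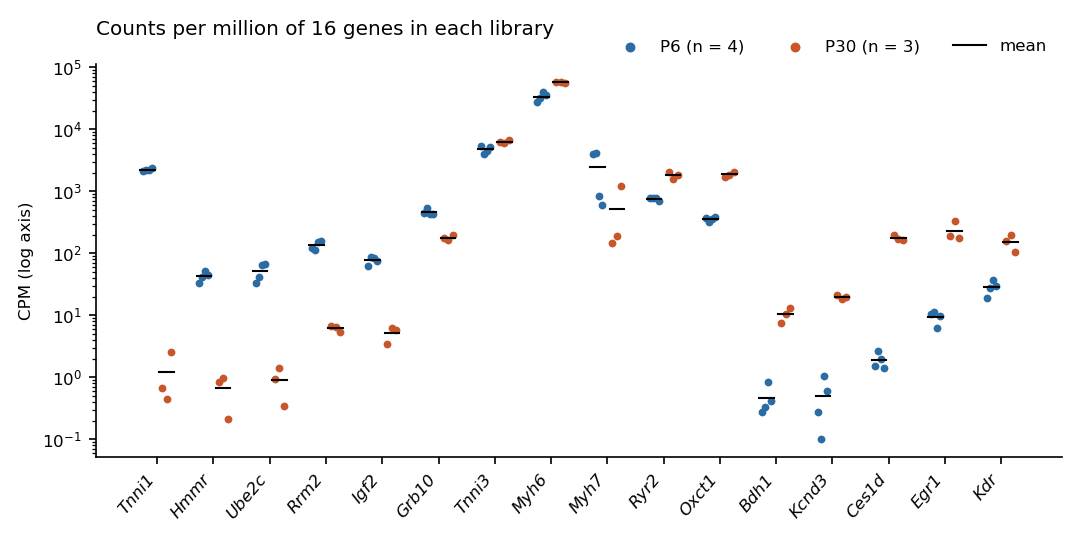
CPM (log axis) of 16 genes in each of the 4 P6 libraries (blue) and 3 P30 libraries (orange), with black lines at the group means. The points of the 2 ages did not overlap for any gene shown except Myh7, whose P6 libraries lay between 590 and 4205 CPM and whose P30 libraries lay between 148 and 1194 CPM.

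Of 12561 genes tested, 3307 were higher and 3490 lower at P30 (edgeR's quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05), and 1331 and 1561 of these differed by at least 2-fold. The biological coefficient of variation was 18.3%. The CPM of 56.6% of tested genes did not overlap between the ages, against 5.71% by chance for 4 libraries against 3. The split into higher and lower depended on the scaling: with library totals in place of TMM factors, 2408 genes were higher and 4658 lower, and the median log2 fold change of all genes moved from -0.02 to -0.20. In a principal component analysis of log CPM the first component held 74.3% of the variance and parted the ages, and the next, with 9.37%, parted P6a and P6b from P6c and P6d.

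The 10 largest falls among well-counted genes were those of Tnni1, Vash2, Tmsb10, Hmmr, Ccnb1, Ube2c, Cdca3, Krt18, Spc25 and Birc5. Tnni1 (chromosome 1, 135779434 to 135810989, plus strand, GRCm38) had an edgeR adjusted p of 5.2e-07, and its log2 fold change was -11.92 without P30c. Vash2, which encodes a tubulin carboxypeptidase, went from 37.8 ± 4.93 to 0.238 ± 0.112 CPM, and Tmsb10, an actin-binding peptide, fell 128-fold to 0.183 ± 0.0834 CPM, both near the level of 3 counts in a P30 library (0.155 to 0.193 CPM). Krt18, a keratin of simple epithelia, fell from 34.6 ± 15.1 to 0.776 ± 0.284 CPM. Ccnb1, Ube2c, Cdca3, Spc25 and Birc5 act in mitosis; Ccnb1 had a log2 fold change of -5.83 ± 0.46, and -6.79 without P30b. The 10 largest rises among well-counted genes were those of Ces1d, Egr1, Rhbdl3, P2ry1, Ogdhl, Fos, Csf1, Slc25a29, Cyr61 and Ly6a. Egr1 and Fos also belong to the immediate early and dissociation-associated list treated below. Ces1d, a carboxylesterase that hydrolyses lipid esters (chromosome 8, 93166068 to 93197838, minus strand), rose from 1.89 ± 0.543 to 175 ± 17.1 CPM, with an edgeR adjusted p of 1.7e-07. Ogdhl, a relative of the 2-oxoglutarate dehydrogenase subunit Ogdh, rose from 9.37 ± 2.57 to 169 ± 9.79 CPM, and Slc25a29, a mitochondrial carrier of basic amino acids, from 1.92 ± 0.595 to 27.5 ± 4.66 CPM. P2ry1, a purinergic receptor, reached 55.2 ± 3.81 CPM from 3.11 ± 1.17, and Csf1, the macrophage growth factor, 127 ± 31.4 CPM from 8.12 ± 3.01.

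Cell cycle genes fell without exception among those tested. All 35 genes of mitosis and cytokinesis were lower at P30, and all 37 genes of DNA replication, with the same counts adjusted over the list alone. The median log2 fold changes were -4.07 and -1.97. Ube2c, a ubiquitin-conjugating enzyme of the anaphase-promoting complex, went from 51.8 ± 17.2 to 0.907 ± 0.537 CPM, and Rrm2, the regulated subunit of ribonucleotide reductase, from 136 ± 21.8 to 6.19 ± 0.629 CPM. Rrm1, the other subunit of that enzyme, fell by 1.99 ± 0.13 on the log2 scale, and the proliferation marker Mki67 by 2.93 ± 0.44. Cenpa, the centromeric histone, kept 24.2 ± 6.31 CPM at P30 against 67.2 ± 8.17 CPM at P6. Tested as sets against all other genes by camera, mitosis had an adjusted p of 2.1e-29 and DNA replication of 9.1e-23; with an estimated correlation the adjusted p was 0.185 and 0.0822.

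Some sarcomere genes moved from fetal to adult forms. The fetal list also holds genes of smooth muscle and the cytoskeleton, so its counts are not of sarcomere isoforms alone. Of 12 fetal and early postnatal sarcomere genes, 6 were lower and 1 higher at P30, and of 27 adult sarcomere genes, 16 were higher and none lower; adjusted over the list alone, the counts were 6 lower and 1 higher, and 17 higher and 1 lower. That no adult sarcomere gene was lower depended on the scaling and on single libraries: 15 were higher and 5 lower with library totals, 2 were lower without P6b and 1 without P30c. Myh6, the adult alpha-myosin heavy chain and the most counted gene, rose from 33636 ± 5693 to 57300 ± 2252 CPM (log2 fold change 0.77 ± 0.12), Tnni3, the adult troponin I, from 4751 ± 605 to 6310 ± 351 CPM, and Xirp2, an actin-binding protein of the intercalated disc, from 43.9 ± 1.97 to 277 ± 32.3 CPM. Myl9, a smooth muscle myosin light chain, went from 478 ± 56.8 to 129 ± 93.0 CPM (log2 fold change -1.90 ± 0.38, and -2.67 without P30c). Acta1, the skeletal actin counted here among the fetal genes, went the other way, from 207 ± 99.7 to 1148 ± 355 CPM. Cnn1, in the fetal list but also listed as a smooth muscle marker, fell by 3.82 ± 0.44 on the log2 scale. Of the light chains in the fetal list, Myl4 fell by 1.87 ± 0.46, and Myl7 did not pass the test (log2 fold change -1.60 ± 1.23). Actc1, the cardiac actin, and Tpm1 did not pass the test, with log2 fold changes of 0.20 ± 0.13 and 0.25 ± 0.10. Tpm1 had an edgeR adjusted p of 0.055, and as low as 0.0151 with 1 library left out. By camera the adjusted p was 0.0045 for the fetal list and 2.1e-05 for the adult list, and 0.128 for each with an estimated correlation.

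Myh7, the beta-myosin heavy chain of the fetal ventricle, had a log2 fold change of -2.24 ± 0.91 and an edgeR adjusted p of 0.060. Its level parted the P6 libraries: 4058 and 4205 CPM in P6a and P6b, and fewer in P6c and P6d, with 590 CPM in the latter. Without P30c the edgeR adjusted p was 0.0066 and the log2 fold change -3.83; this library held 1194 CPM against 148 and 193 CPM in P30a and P30b.

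Shares within pairs of paralogous genes gave a measure free of library scaling. The share passed an exact permutation test (two-sided, p = 0.0286, the smallest that 35 splits of 7 libraries allow, and 0.0416 after Benjamini-Hochberg adjustment over 16 pairs) in 11 pairs. Tnni3 made up 67.9% ± 2.94 (SD, n = 4) of troponin I counts at P6 and 99.98% ± 0.0167 (SD, n = 3) at P30. The heart and muscle subunits of cytochrome c oxidase gained on their ubiquitous counterparts: Cox6a2 went from 77.8% (76.5% to 80.5% in single libraries) to 93.7% ± 0.395 of its pair, Cox8b from 48.9% ± 3.85 to 73.0% ± 2.60 and Cox7a1 from 25.3% ± 1.85 to 46.4% ± 4.44. For Cox6a and Cox8 the ubiquitous members fell, Cox6a1 by 1.72 ± 0.16 and Cox8a by 1.74 ± 0.16 on the log2 scale, while Cox8b itself had a log2 fold change of -0.25 ± 0.22 that did not pass the test. In the Cox7a pair Cox7a2 fell by 0.74 ± 0.18 and Cox7a1 rose by 0.61 ± 0.23, a call that was lost without any of P6b, P6c, P30a and P30c (edgeR adjusted p up to 0.197). Hexokinase 2 rose from 23.6% ± 2.52 to 38.1% ± 1.44 of hexokinase 1 and 2 counts, Ldhb from 42.0% ± 1.52 to 52.0% ± 2.57 of lactate dehydrogenase, and Slc25a4, the heart form of the adenine nucleotide carrier, from 87.5% ± 0.685 to 93.3% ± 0.216. Ckm rose from 93.9% ± 0.340 to 97.5% ± 0.298 of cytosolic creatine kinase counts, and Slc2a4, the insulin-responsive glucose carrier, from 94.6% ± 0.701 to 97.1% ± 0.659 of its pair with Slc2a1. Cpt1b went from 7.44% ± 0.744 to 19.5% ± 2.45 of its pair with Cpt1a, though Cpt1b had only 13.6 ± 0.441 CPM at P6 and overlaps Chkb, so its counts are uncertain. Actc1 was the exception in direction, with 99.2% ± 0.267 of its pair with Acta1 at P6 and 96.2% ± 1.32 at P30. The share of Myh6 in the sum of Myh6 and Myh7 was 92.9% ± 6.14 at P6 and 99.1% ± 1.07 at P30, a difference within the spread between libraries (exact permutation p = 0.229). The pairs led by Myl2, Myl3 and Eno3 did not pass either, each with shares above 99% at both ages. Eno1 had only 1.23 ± 0.432 CPM at P6 and 0.493 ± 0.137 CPM at P30. The treatment of multi-mapping reads is not given, and whether it lowered the Eno1 count was not tested, so the Eno3 share is uncertain.

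**Figure D2:**
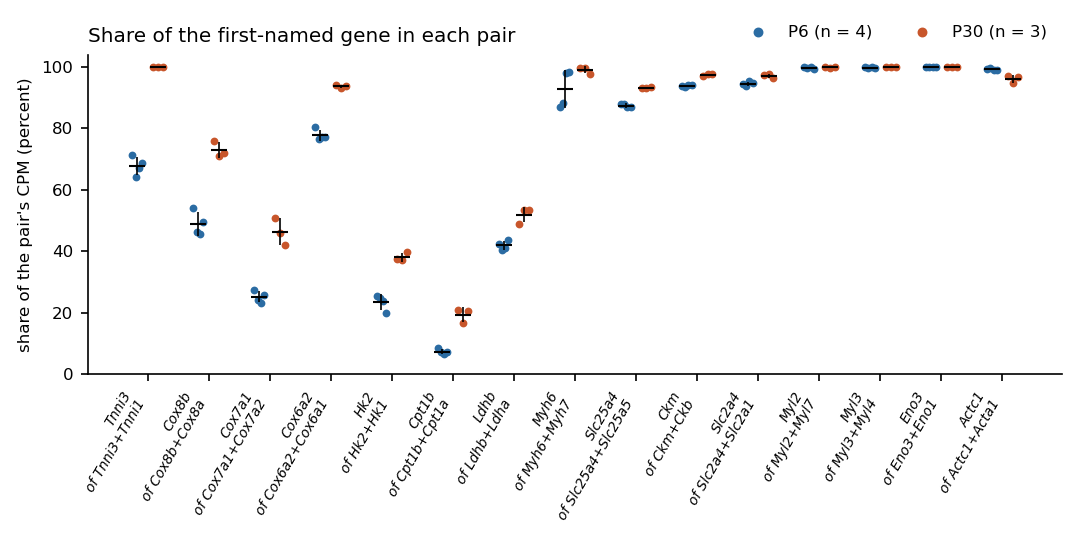
Share of the first-named gene in the summed CPM of each of 15 gene pairs, in percent, for each P6 (blue) and P30 (orange) library, with the mean and SD in black. Tnni3 went from 67.9% to 99.98% of its pair, and the shares of Cox8b, Cox7a1, Cox6a2, Hk2, Cpt1b and Ldhb were higher in each P30 library than in any P6 library.

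Among genes of energy metabolism, the enzymes that break down ketone bodies and branched-chain amino acids stood out. Of 21 tested, 18 were higher at P30 and none lower, with the same counts adjusted over the list alone, and the median log2 fold change was 1.15; 1 gene was lower without P6b or with library totals. Bdh1, which interconverts the ketone bodies, rose from 0.464 ± 0.251 to 10.4 ± 2.89 CPM (log2 fold change 4.29 ± 0.37, and 4.89 without P6c), and Hibadh, an enzyme of valine breakdown, from 298 ± 22.2 to 543 ± 11.2 CPM. Camera gave an adjusted p of 5.4e-16, and the adjusted p was 0.0822 with an estimated correlation. In the citric acid cycle and pyruvate dehydrogenase list, 14 of 22 genes rose and 1 fell, or 15 and 1 adjusted over the list alone; 3 fell with library totals and 2 without P6b. Ogdh rose from 2556 ± 96.7 to 5247 ± 214 CPM. The gene that fell was Idh2, by 0.29 ± 0.08 on the log2 scale, a call that was lost without P30a or without P30b (edgeR adjusted p up to 0.0756). For this list the camera adjusted p was 0.0067, and the adjusted p was 0.547 with an estimated correlation.

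Fatty acid and glycolytic genes went both ways. Of 30 genes of fatty acid uptake and oxidation, 10 were higher and 6 lower, with the same counts adjusted over the list alone; with library totals the counts were 5 and 10. Lpl, the lipase that releases fatty acids from lipoproteins, rose from 2082 ± 239 to 5296 ± 513 CPM, whereas Fabp3, the cardiac fatty acid binding protein, fell from 4036 ± 871 to 1966 ± 147 CPM and Cpt1a from 170 ± 17.3 to 75.4 ± 9.96 CPM. Of 23 glycolytic and lactate genes, 7 were higher and 4 lower, or 5 and 6 with library totals, with 7 and 4 adjusted over the list alone, and 2 were lower without P30a or without P30c. Aldoa rose from 2828 ± 78.8 to 4568 ± 139 CPM and Slc2a4 from 273 ± 18.6 to 731 ± 14.9 CPM. Neither list was called by camera, with adjusted p of 0.78 and 0.21; their medians of 0.09 and 0.13 were opposite in sign to their means of -0.10 and -0.04.

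Nuclear genes of the respiratory chain gave 12 higher and 22 lower of 75 tested, or 10 and 21 adjusted over the list alone; with library totals the counts were 6 and 39. As a set the list was not called (adjusted p of 0.24 by camera; exact permutation p of the median = 0.286). Cox8a went from 335 ± 53.4 to 101 ± 17.1 CPM, Cox6b1, another cytochrome c oxidase subunit, from 1239 ± 253 to 836 ± 122 CPM, and Atp5b, the catalytic subunit of ATP synthase and among the 5 most counted genes, from 11635 ± 434 to 13256 ± 157 CPM. The counts of this list changed with transcript length. Among genes with at least 10 CPM the median log2 fold change ran from -0.29 in the decile with the shortest transcripts to 0.23 in the decile with the longest, and with a smooth length trend taken out of each library the list gave 38 higher and 11 lower. The number of lower genes was 11 without P30b and 35 without P6b, and the call of Cox6b1 was lost without P30b (edgeR adjusted p = 0.0669). The call of Atp5b was lost without any of P6a, P6c and the P30 libraries (edgeR adjusted p up to 0.103).

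Genes of excitation-contraction coupling and ion channels rose more often than they fell. Of 22 coupling and T-tubule genes, 11 rose and 3 fell, and of 32 ion channel and gap junction genes, 17 rose and 4 fell, with the same counts adjusted over the list alone. Atp2a2, the calcium pump of the sarcoplasmic reticulum, rose from 17162 ± 883 to 30961 ± 226 CPM (log2 fold change 0.85 ± 0.07), and Hrc, a calcium-binding protein of the same store, from 118 ± 27.9 to 429 ± 67.5 CPM. Camk2d, a calmodulin-dependent kinase, fell by 0.33 ± 0.08 on the log2 scale. Kcnd3, a pore subunit of the transient outward potassium current, rose from 0.503 ± 0.418 to 19.8 ± 1.30 CPM (log2 fold change 5.09 ± 0.47, and 6.21 without P6c). The camera adjusted p was 0.070 for the coupling list and 0.014 for the channels; with an estimated correlation the adjusted p of the channels was 0.415. With library totals the coupling list gave 8 higher and 7 lower and the channels 16 and 7; without P30a or without P30b 2 channel genes were lower.

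Many fetal growth, ribosomal protein and splicing regulator genes were lower. Of 20 imprinted and fetal growth genes, 15 were lower and none higher, with the same counts adjusted over the list alone. Grb10, an inhibitor of growth factor signalling, went from 462 ± 55.2 to 178 ± 14.1 CPM, Slc38a4, an amino acid carrier, from 155 ± 18.1 to 52.7 ± 3.71 CPM, and H19 from 6.88 ± 4.18 to 0.548 ± 0.332 CPM. Camera gave an adjusted p of 7.7e-07, and the adjusted p was 0.126 with an estimated correlation. Of 75 cytosolic ribosomal protein genes, 62 were lower and none higher, or 63 lower adjusted over the list alone, with a median log2 fold change of -0.78. Rps29 went from 71.4 ± 23.3 to 19.2 ± 7.07 CPM. These transcripts are short, with a median of 937 bases by the longest annotated coding transcript of each gene. With the length trend removed 44 were lower and 1 higher, and with 1 library left out 52 to 67 were lower. Their counts may also be split with pseudogenes. As a set they had a camera adjusted p of 1.5e-08, and the adjusted p was 0.547 with an estimated correlation. Of 23 RNA splicing regulators, 12 fell and 1 rose, or 13 and 2 adjusted over the list alone, with 2 that rose without P6b and 0 without P30b; Rbm24, a muscle splicing factor, went from 547 ± 60.9 to 237 ± 15.0 CPM and Srsf3 from 223 ± 41.7 to 80.5 ± 8.70 CPM (camera adjusted p = 0.015, and adjusted p = 0.527 with an estimated correlation).

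Transcription regulators of the heart and its metabolism divided into 9 higher and 12 lower of 34 tested, with the same counts adjusted over the list alone. Ppargc1a, a coactivator of mitochondrial genes, fell from 478 ± 93.6 to 200 ± 19.6 CPM, and Hopx, a homeodomain protein, from 872 ± 113 to 269 ± 26.0 CPM. Esrra and Ppara, nuclear receptors of oxidative metabolism, rose by 0.39 ± 0.10 and 0.42 ± 0.10 on the log2 scale. Srf, the serum response factor, had a log2 fold change of 0.08 ± 0.12 and did not pass the test. Of 22 cytoskeletal actin and MRTF-SRF target genes, 6 fell and 3 rose, or 6 and 2 adjusted over the list alone, and 1 rose without P30b or with library totals. Flna, filamin A, went from 221 ± 20.7 to 144 ± 16.7 CPM, while Cyr61, a secreted matricellular protein, rose from 51.8 ± 16.7 to 714 ± 143 CPM. By camera the adjusted p of these lists was 0.54 and 0.53. Their medians were 0.03 and -0.03, and -0.15 and -0.21 with library totals, a shift that all genes shared, and the regulators' mean of -0.15 and camera direction were opposite in sign to their median.

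The natriuretic peptide and hypertrophy list gave 3 higher and 4 lower of 12, or 5 and 6 adjusted over the list alone (adjusted p of 0.83 by camera), and 5 were higher without P6c. Ankrd1, a stretch-responsive ankyrin repeat protein, fell from 1662 ± 16.6 to 971 ± 250 CPM and Xirp1 rose from 582 ± 139 to 989 ± 98.3 CPM. Nppa, the atrial natriuretic peptide, had 338 ± 146 CPM at P6 and 344 ± 193 CPM at P30, and Nppb 201 ± 118 and 408 ± 41.3 CPM, neither past the test (edgeR adjusted p = 0.96 and 0.051; Nppb passed without P6c or without P6d, at 0.0235 in the former case). Clock genes went both ways, 6 higher and 5 lower of 18, with the same counts adjusted over the list alone, and 3 higher and 8 lower with library totals. Arntl, the core activator of the clock, rose from 7.56 ± 1.39 to 39.3 ± 5.09 CPM. Nr1d2, a repressor in the same loop, fell from 93.3 ± 16.6 to 56.0 ± 10.7 CPM. The clock list had an adjusted p of 0.87 by camera, with the median and mean negative and the test's direction positive. The time of day of collection was not compared between the ages, so its effect on clock genes cannot be told apart from that of age.

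Immediate early and dissociation-associated genes were higher at P30 in 14 of 23 cases and lower in 1, with the same counts adjusted over the list alone. Egr1 rose from 9.42 ± 2.20 to 230 ± 85.6 CPM, Dusp1, a phosphatase of MAP kinases, from 92.7 ± 18.7 to 521 ± 69.5 CPM, and Hspa1a, an inducible heat shock protein, from 0.773 ± 0.445 to 21.2 ± 8.48 CPM. Jund fell by 0.69 ± 0.12 on the log2 scale. As the list's name says, dissociation of the cells can also raise these genes. Whether handling differed between the ages was not tested, so an effect of age cannot be told apart from one of isolation. Fos rose from 26.3 ± 18.3 to 439 ± 112 CPM, and was uneven within P6, with 45.0 and 38.3 CPM in P6a and P6b and 6.29 and 15.5 CPM in P6c and P6d. As a set these genes had a camera adjusted p of 3.1e-05, and the adjusted p was 0.517 with an estimated correlation.

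Interferon response genes were higher in 20 of 23 cases and antigen presentation genes in 14 of 17, with none lower in either list. Adjusted over the list alone the counts were 21 and 15. At the threshold over all genes they ran from 16 to 23 and from 12 to 15 with 1 library left out. The count table held 28 and 19 of these genes. Expression at 1 age alone can satisfy the low-count filter, so the filter may partly set these counts. H2-D1, a class I histocompatibility molecule, rose from 18.0 ± 3.41 to 92.8 ± 46.3 CPM. B2m, its light chain, had 32.0 ± 11.5 and 63.3 ± 33.4 CPM, with overlapping libraries and a call that was lost without any of P6a, P6b, P6c, P30a and P30b (edgeR adjusted p up to 0.215, without P30b). The camera adjusted p was 3.1e-05 and 7.9e-05, and the adjusted p was 0.547 and 0.517 with an estimated correlation. P30b, which had the most H2-D1 (142 CPM), also had the most endothelial and leukocyte marker counts. Since the virus was given on day 1 at both ages, an effect of age on these genes cannot be told apart from the longer time since the virus at P30.

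**Figure D3:**
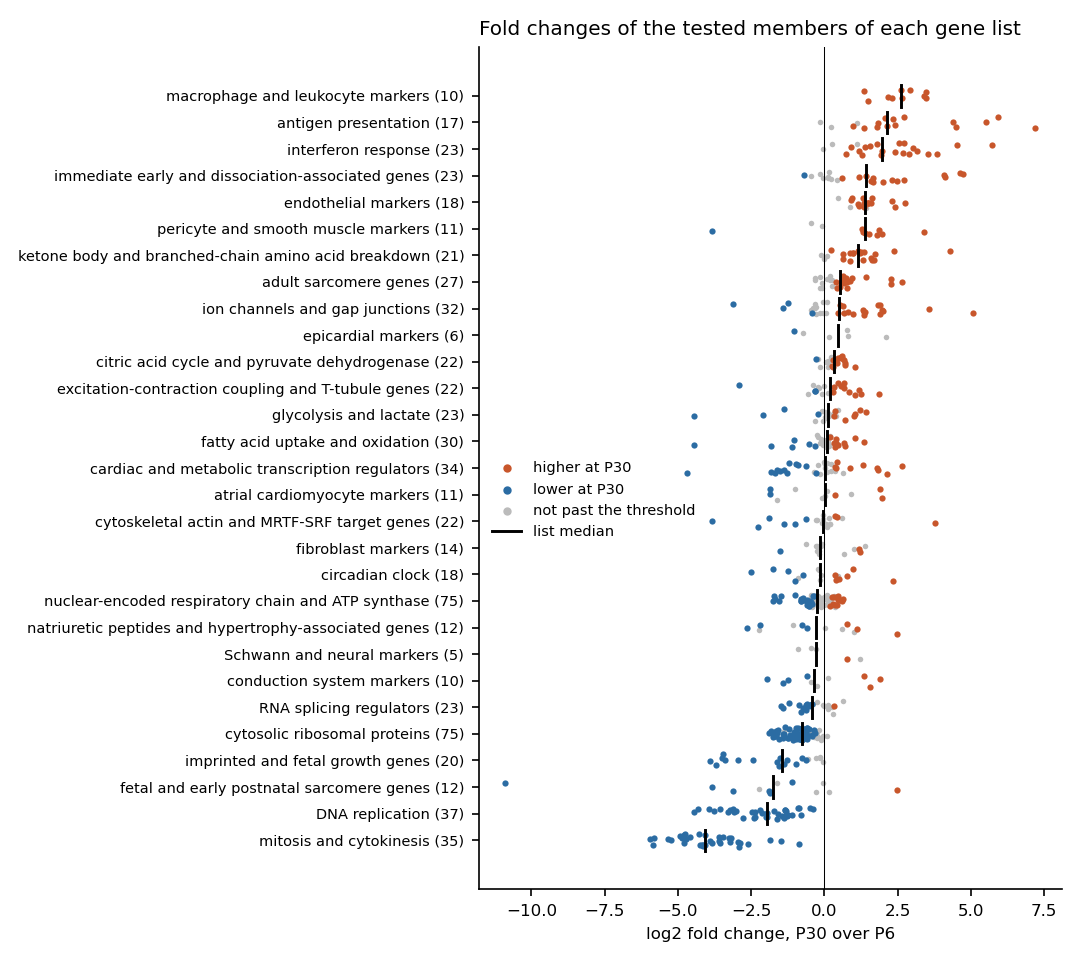
Log2 fold change (P30 over P6) of each tested member of 29 fixed gene lists, with the number tested in parentheses; orange and blue points passed the threshold upward and downward, grey points did not, and black bars are list medians. Medians ran from -4.07 for mitosis and cytokinesis to 2.63 for macrophage and leukocyte markers.

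Markers of other cell types served as a check on the sort. Of 18 endothelial markers, 15 were higher at P30 and none lower, as were all 10 macrophage and leukocyte markers tested and 8 of 11 pericyte and smooth muscle markers, of which 1 was lower; the counts were the same adjusted over the list alone. Kdr, the receptor for vascular endothelial growth factor, rose from 28.4 ± 7.64 to 153 ± 46.9 CPM, Pecam1, an endothelial adhesion molecule, from 27.1 ± 5.85 to 62.8 ± 27.1 CPM, and Pdgfrb, the pericyte growth factor receptor, from 12.8 ± 2.69 to 37.5 ± 11.6 CPM. Lyz2, a lysozyme of myeloid cells, had 1.86 ± 0.655 and 8.71 ± 5.66 CPM (log2 fold change 2.30 ± 0.46, and 1.65 without P30b). The count table held 20 leukocyte markers, and only those past the low-count filter were tested. Expression at 1 age alone can satisfy that filter, so the result for all those tested is partly set by it. Without P30b 4 leukocyte markers passed, and without P30a 5 pericyte markers; 2 pericyte markers were lower without P30b. The camera adjusted p was 3.1e-05 for endothelial, 0.024 for leukocyte and 0.070 for pericyte markers, and the adjusted p of the called lists was 0.527 and 0.551 with an estimated correlation.

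Fibroblast markers gave 2 higher and 1 lower of 14: Fbln1, an extracellular matrix glycoprotein, and Ddr2, a collagen receptor, rose by 1.20 ± 0.26 and 1.22 ± 0.33, and Postn, another matrix protein, fell by 1.51 ± 0.28 on the log2 scale. The call of Ddr2 was lost without P30b (edgeR adjusted p = 0.0705), and the list gave 1 higher and 2 lower without P30b and 4 higher without P6b or without P30a. Epicardial markers gave 1 lower of 6 (Tbx18), Schwann and neural markers 1 higher of 5 (Prnp), atrial markers 3 higher and 2 lower of 11, and conduction markers 3 higher and 4 lower of 10. Adjusted over the list alone these counts were the same. With 1 library left out, Schwann markers gave 2 higher without P6c and 1 lower without P6b, and 1 atrial marker was lower without any of P6b, P6d, P30a and P30c. The camera adjusted p of the 5 lists was 0.86, 0.92, 0.75, 0.70 and 0.70. The direction of the test was upward for fibroblast and Schwann markers although their medians were -0.13 and -0.30. The atrial median was 0.03 with a mean of -0.11, and the median was -0.15 with library totals, by the shift common to all genes. No member of the mitochondrially encoded, red blood cell or adipocyte lists was tested, and the mitochondrially encoded genes had no entry in the count table.

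The summed markers of these cell types were small shares of all counts. Endothelial markers made up 0.0302% ± 0.00783 (SD, n = 4) of counts at P6 and 0.0740% ± 0.0252 (SD, n = 3) at P30, and leukocyte markers 6.9e-04% ± 1.7e-04 and 0.00326% ± 0.00216, each with an exact permutation p of 0.0286 and 0.0629 after adjustment over 11 measures. Fibroblast markers lay between 0.0246% and 0.0561% at P6 and between 0.0232% and 0.0425% at P30 (exact permutation p = 0.80). The 10 most counted genes of each library held 15.0% ± 0.674 of counts at P6 and 18.1% ± 0.163 at P30, and sarcomere genes 14.6% ± 0.723 and 16.1% ± 0.347. None of the 11 measures of composition passed after adjustment. The smallest p that the exact test allows, 0.0286, became 0.0629 here, so this does not show that composition stayed the same.

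**Figure D4:**
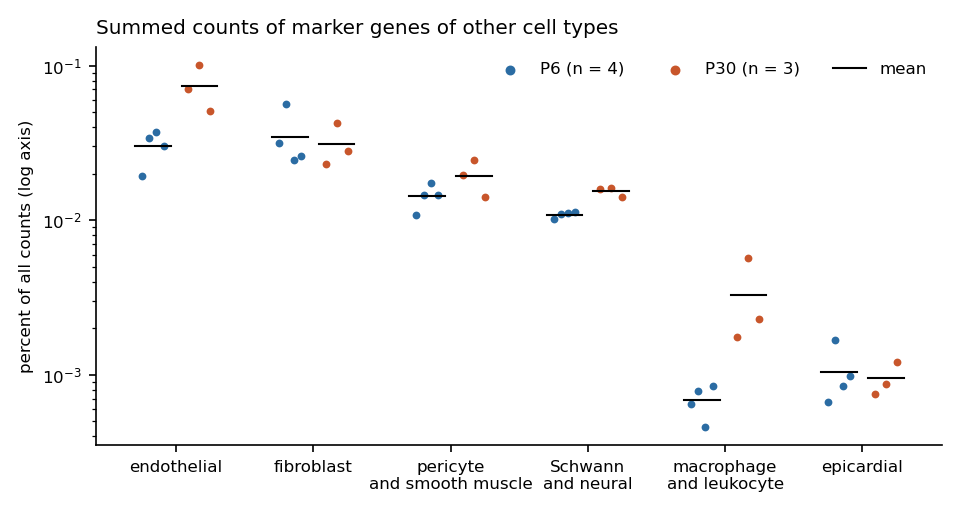
Summed counts of marker genes of 6 other cell types as a percent of all counts (log axis) in each P6 (blue) and P30 (orange) library, with black lines at the means. Endothelial markers lay between 0.0193% and 0.0374% at P6 and between 0.0507% and 0.101% at P30, and fibroblast markers overlapped.

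The set tests carry a limit of their own. Camera with its preset correlation of 0.01 called 15 of 29 lists, none was called with an estimated correlation, and an exact permutation test of each list's median gave at best p = 0.0286, or 0.0592 after adjustment over 29 lists. Fry, which does not compare a list with other genes, called 20 lists; the 5 that camera did not call were glycolysis (adjusted p = 1.0e-03 by fry), excitation-contraction coupling (0.0029), pericyte markers (0.0234) and Schwann markers (0.0149) upward, and the transcription regulators (0.0149) downward. The counts of individual genes above do not rest on these set tests.

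The authors' deposited table of the same comparison, made with DESeq2, listed 3651 genes higher and 3428 lower at P30 with an adjusted p under 0.05. Of the 6797 genes called here by edgeR, 6630 were called in the authors' deposited table in the same direction and none in the opposite direction. Among genes not tested here because of low counts, the authors' deposited table called 333, of which 284 were higher at P30. Without the low-count filter the median log2 fold change of all genes here was 0.22, against -0.02 with it. Reads on olfactory and vomeronasal receptor genes, described below, were also more frequent at P30. Whether such scattered reads account for part of the 284 was not tested.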

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

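Of the tests below, the comparison of receptor genes with sequencing depth and the size of the background that their reads imply were chosen after seeing the result; the other 2 tests of receptor reads had their predictions written before, and the search for single libraries that stand apart was fixed beforehand. Reads on genes of olfactory and vomeronasal receptors, which no comparison of the report uses, were more frequent at P30. Olfr genes had a mean of 32.2 CPM at P30 (13.8 to 49.1) and 3.77 CPM at P6, Vmn1r genes 3.29 and 0.0909 CPM, and Vmn2r genes 5.62 and 1.22 CPM. Of 1457 receptor genes, 502, 116 and 318 had a count in P30a, P30b and P30c, and 12 to 36 in the P6 libraries.

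Depth did not account for these reads, since P6c, with the most counts, had only 36 receptor genes with a count. Transcription of a few receptor genes did not account for them either: the 10 genes with the most reads held 20.4% of receptor reads at P30, against 83.5% at P6. Genomic DNA in the libraries could spread reads over silent genes, and would then give male cells fewer reads on chromosome X than on autosomes; the ratio on genes with no count at P6 was 0.525, 0.762 and 0.633 in P30a, P30b and P30c. The highest of these, 0.762 from 52 reads in P30b, lay above the limit of the prediction, so this test leaves the source open, and no other biological explanation was tested. For the genes tested here the reads are too few to move the comparison, because the background they imply exceeded 10% of the P30 level in 0 of 3307 genes called higher. Genes below the low-count filter, which the authors' deposited table also tested, were not covered.

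A single P6 library stood apart from the other 3 in 11 of 165 groups of 4 values, by the ratio of its gap to the range (critical value 0.829). Chance marks about 1 in 20 groups, or 8.2 here. P6b was the library apart for Acadvl (0.865), Hibadh (0.887), Grb10 (0.862), Tef (0.881), Postn (0.830), H19 (0.879) and the share of Ckm (0.846). P6d was apart in 2 groups, among them Tmsb10 (0.919), and P6a for Ppargc1a (0.896) and the share of Cox6a2 (0.856). The number of groups is near that of chance, and no explanation was tested for the share that fell to P6b.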

How the results depend on the processing

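The alternatives for transcript length, GC content, subsets of P6, background, column letters and list medians were added after seeing the data. The numbers of genes higher (3307) and lower (3490) stayed within 1.5 times under every alternative but glmTreat, which asks for more than 2-fold and gave 582 and 763. The counts of genes changed at least 2-fold (1331 and 1561) were also 582 and 763 by glmTreat, and 623 and 733 with a mean CPM of at least 10, where 8234 genes were tested. In the authors' deposited table, asking for 2-fold left 1637 higher and 1557 lower. Leaving out each library gave 2788 to 3460 higher and 2885 to 3577 lower, and 1227 to 1456 and 1481 to 1560 at 2-fold. No gene was called in opposite directions by any alternative except 1 with length and GC trends removed. Of 15 gene lists called by camera, 0 were called with an estimated correlation. Among named genes, 2912 of the alternative values kept their status as called or not called. A call was lost in 194 and gained in 44, and 1 value turned. That was Atp5o, with a log2 fold change of 0.044 with the length trend removed (edgeR adjusted p = 0.57) against -0.37, and the cause was not tested. Without each library in turn, 105 of 124 named genes past the threshold stayed past it. The differences between ages in 128 alternative values of gene-pair shares and 88 of composition moved by less than the spread between libraries; with a library left out the exact test cannot reach 0.05, so no call was tested there. A replicate block by column letter, the letters being tied to no title number, gave 2895 higher and 3077 lower; deviations of same-letter libraries correlated at -0.10, 0.09 and -0.20, and only b correlated best with its own letter. A replicate block by title number was not run, since the columns carry letters, nor were the alternatives that leave out mitochondrially encoded genes, which have no entry. Depth limits genes near 3 counts, 0.0583 to 0.283 CPM.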

Other observations

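The following 5 genes were chosen after their values were seen, and no list covers them as a group. Rpl3l, the muscle-specific relative of the ribosomal protein Rpl3, rose from 22.7 ± 9.23 to 232 ± 32.8 CPM (log2 fold change 3.36 ± 0.27), and Rpl3 fell from 106 to 35.1 CPM. Eef1a2, the muscle and nerve form of elongation factor 1 alpha, rose from 63.6 to 209 CPM, and Eef1a1 fell from 441 to 66.0 CPM. Kcne1, an auxiliary potassium channel subunit, fell from 693 to 80.5 CPM.

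The sex-linked genes parted 1 library from the rest. P6a had 53.4 CPM of Xist and 0 of Ddx3y, and the other 6 libraries had 79.0 to 109 CPM of Ddx3y and at most 0.695 CPM of Xist, so that the single library with female reads was at P6. Nr4a1, a member of the immediate early list, was chosen after its values were seen. It had 421 and 475 CPM in P6a and P6b, 63.4 and 63.5 CPM in P6c and P6d, and 223 to 346 CPM at P30.

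Of the tests below, the difference between endothelial and fibroblast markers was chosen after seeing the result, and the removal of length and GC trends after seeing the trends; the other predictions were written before their results. The fall of ribosomal protein transcripts could come from a transcript length and GC trend between libraries. The correlation of log2 fold change with log length was 0.17. Libraries of the same age also differed by length: deviations from the age mean correlated with log length at 0.36 in P6b and -0.34 in P6d. With both trends taken out the list median was -0.48, against -0.78 as reported. Sets of genes matched to it had a median of -0.30 and at lowest -0.59 in 10000 draws. The trends as modelled thus account for part of the fall. Lengths were those of the longest annotated coding transcript, which may overstate these transcripts. The draws also took genes singly, while the list had an estimated correlation of 0.63. A larger effect of length is therefore not excluded. Scaling by a few abundant genes does not account for it, with a median of -0.76 at the closest to 0 of 4 other scalings. A fall in ribosomal transcripts per cell between P6 and P30 remains possible, and no test of it was run beyond these.

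The rise of endothelial, pericyte and leukocyte markers could come from a lower share of cardiomyocytes among the sorted cells. That would raise fibroblast markers alike only if the mix of other cells and their expression stayed the same, which was not tested. The endothelial median exceeded the fibroblast median by 1.53 on the log2 scale. Another split, P6a, P6b and P6d against the rest, gave an absolute difference of 1.59 (exact permutation p = 0.0571). That split keeps all P30 libraries on 1 side and so holds part of the age difference itself. It does not show that chance gives as much, and with so few splits the test cannot decide, so this explanation stays open. More endothelial cells carried through the sort at P30 would raise all endothelial markers by 1 factor only if their expression per cell did not change with age. The heterogeneity p was 1.6e-09, yet none of the 18 was lower, with log2 fold changes of 0.46 to 2.74, so this test leaves the question open. Kdr, at 28.4 and 153 CPM, was among the most counted of them. The sort was on a label that depends on Cre expressed from the cardiac troponin T promoter and was meant to remove such cells; how well it did so, and how many of these genes cardiomyocytes express, was not tested.

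Whether chance divisions of the libraries give as much was tested by the 35 splits into 4 and 3. For genes, 1 of 35 splits, the real one, gave 6797 genes past the threshold, and the highest other gave 0. Every other split puts libraries of both ages into at least 1 group, which widens the spread within it. The 0 therefore does not measure what chance alone gives, and the real split was only the most extreme of 35. For the number of lists called by camera, 10 of 35 splits gave at least the real 15 and the highest other gave 18. The other splits also divide the ages unevenly and so hold part of the age difference. This test therefore cannot tell whether chance alone would call as many lists.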
